A study of Mus musculus with 6 samples.

How the data were processed

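RNA-seq libraries from the anterior cingulate cortex of BALB/c mice were compared between 3 replicates with social defeat stress for 5 days and 3 non-stress replicates, as the labels group them. Per the labels' protocols, total RNA was extracted with a column kit, and libraries were made with a SMARTer low-input kit and TruSeq library construction. The SMARTer chemistry starts complementary DNA at the poly(A) tail, so transcripts without one are poorly covered and stretches of A inside a transcript can also be primed. Per the submitters' processing notes, the read trimmer Trimmomatic 0.38, the aligner HISAT2 and the transcript quantifier StringTie were used, with genome build GRCm38 (mm10). The step that made the counts, the parameters, the annotation release, the treatment of reads that map to several genes and the use of strand are not given in the sources used here. Reads from overlapping genes on opposite strands, and from near-identical copies, therefore cannot be separated with certainty.

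The authors deposited one table of whole-number counts per gene with NCBI Gene IDs and symbols, 1 column per library. The deposited counts were used unchanged. They had not been normalised: the totals ranged from 41623899 to 47212982 per library. In each library, genes with 2 counts were 1.42 to 1.49 times as frequent as the mean of genes with 1 and 3 counts, as would be seen if many read pairs added 2 to a gene. Counts are then not independent molecules, and floors cover the counting error of independent counts only. A count of 0 was given a floor of 3 counts, which is 0.0635 to 0.0721 CPM (counts scaled to the library's total) in a single library. Where StringTie gives counts it derives them from coverage, so small counts are approximate. BALB/c differs from the reference strain in sequence, most of all in the MHC region, which can lower the counts of class I genes in every library.

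Of 45777 genes, 29726 had a count above 0 in at least 1 library, and edgeR's filterByExpr kept 19227 for testing. These held 99.9% of the counts of each library. Library sizes were scaled by TMM, with factors from 0.996 to 1.00. Stress was compared with non-stress by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with group as the single term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 and no fold limit. All tests were two-sided. The square root of the common dispersion was 0.0856. The prior count for log2 CPM was 2. Fold changes are stress over non-stress, and CPM are given as the mean ± SD of 3 libraries.

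The gene lists, the rule for named genes, the tests and most of the alternatives were fixed before the data were examined. 37 lists covered activity, stress hormone, receptor, calcium and cyclic AMP signalling, synapse and channel genes, cell types of the region and its neighbours, immune responses, and cell stress and metabolism. Lists with fewer than 5 tested members were not tested. That applied to 1 list, of mitochondrially encoded genes, which had been written with another symbol style than the table uses. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 36 lists, with an estimated correlation and fry beside it. Members are also counted with p-values adjusted over the list alone.

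Genes were named by these rules. Of genes past the threshold whose groups did not overlap, and whose symbols were not a Gm number, a Rik or a pseudogene name, the 12 with the largest fold change in each direction were to be named. Directions with fewer than 12 were filled with the smallest p-values under the other conditions, and those genes are said not to pass. The 3 members of smallest p-value of each list described were added, with Fos, Arc, Fkbp5, Crhr1, Nr3c1 and Bdnf. Chromosome positions come from NCBI's gene table for GRCm38, in which 45679 of the table's genes were found. GC content and transcript length came from the GENCODE annotation of GRCm38, with values for 17314 of the 19227 genes tested (90.1%).

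The alternatives were other size factors, no filter or a stricter one of 50 counts in 3 libraries, each library left out in turn, replicate number as a block, DESeq2 1.42.0, limma-voom with and without quality weights, other thresholds and other list tests. Added after seeing the data were the removal of smooth trends on GC content, transcript length and A content from each library, other dispersion settings of edgeR, the removal of those trends together with non-stress 1, and a fit with a separate term for non-stress 2 and 3. That fit leaves non-stress 1 as the only non-stress library compared with stress and assumes that it varies like the others. The division of the non-stress libraries was found in the expression values and is not in the labels.

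The tests were tried on simulated data with the real means, library sizes and group sizes, in 5 simulations of 19227 genes with 200 changed. The edgeR step recovered 32.4% of genes changed 1.25-fold, 77.2% of those changed 1.5-fold, 91.2% at 2-fold and 99.6% at 4-fold, with 7.08% of calls false. Of 20 lists shifted by 0.15 on the log2 scale, camera found 17, and it called 0 others. The simulation did not include the division of the non-stress libraries. It drew each gene independently, so it could not show false list calls that come from correlated members. In the real data the estimated correlation of the ribosomal protein list was 0.473. The changed genes were not drawn from those of lowest expression. Recovery at an adjusted threshold also depends on how many genes change, so these rates need not hold for the real data, where 1 gene passed.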

Results

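RNA sequencing was carried out on the anterior cingulate cortex, a frontal midline region of the brain, of BALB/c mice, an inbred laboratory strain. 3 libraries came from mice exposed to social defeat stress for 5 days, a procedure in which a mouse is repeatedly subordinated by an aggressive one, and 3 came from mice without stress. The deposited table held whole-number counts for 45777 genes. The counts summed to 43104218, 47212982 and 41976809 in non-stress replicates 1, 2 and 3, and to 41623899, 43450933 and 44882821 in stress replicates 1, 2 and 3. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between these samples, which may be technical.

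The libraries did not fall by group alone. Principal component 1 of the log2 CPM (counts scaled to the library's total) of 19227 genes held 34.5% of the variance. On it, non-stress 2 and non-stress 3 lay at 37.4 and 27.4, while non-stress 1 lay at -11.7, close to the stress libraries at -17.9, -20.4 and -14.9. The labels name no batch. Messenger RNA encoded by the mitochondrial genome took 1.76% to 2.40% of the counts in the non-stress libraries and 2.51% to 2.67% in the stress libraries.

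**Figure D1:**
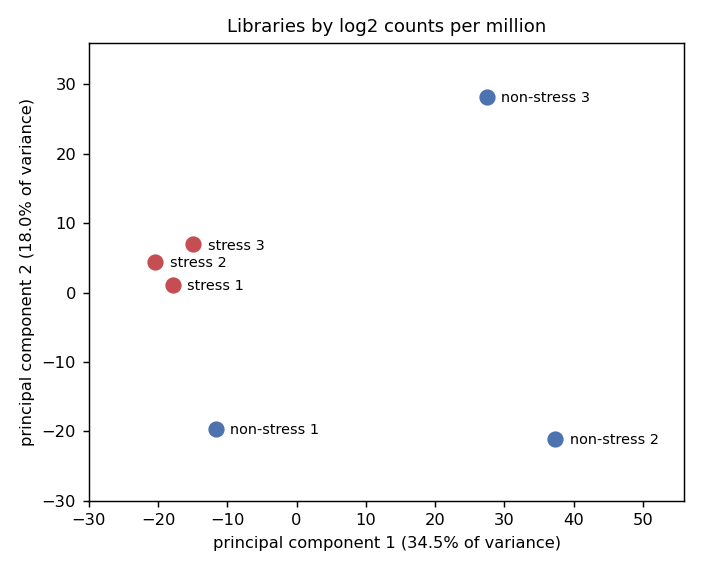
The 6 libraries are plotted by their positions on principal components 1 and 2 of log2 CPM (arbitrary units; blue, non-stress; red, stress), with the share of variance on each axis. Non-stress 2 and 3 lie at 37.4 and 27.4 on component 1, and non-stress 1 lies at -11.7, next to the stress libraries.

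The comparison of stress with non-stress mice addresses how repeated social defeat alters expression in this region, including the receptor, calcium and cyclic AMP pathways that the series title names. Interferon-responsive genes, among them the antigen-presenting MHC class I genes, were lower as a group after stress, with a median fall by 0.23 on the log2 scale over 26 genes. Immediate early genes, which neurons transcribe within minutes of activity, and circadian clock genes were also lower as groups, with median falls by 0.12 and 0.16. The immediate early call was lost without non-stress 1 (adjusted p = 0.0833) and once a trend on sequence composition was taken out (0.0707 with GC content and transcript length, 0.0545 with A content added). Genes for cytosolic ribosomal proteins, for the mitochondrial respiratory chain and for neuropeptides were higher as groups, with median log2 fold changes of 0.12, 0.08 and 0.15, although the respiratory chain call depended on how that trend was taken out (adjusted p = 0.222, or 0.0221 with A content added). These group shifts were small, and each rested on a test that assumes a fixed correlation of 0.01 between genes: with a correlation estimated from the 6 libraries, 0 of the 36 lists tested passed, and the adjusted p of these lists lay between 0.406 and 0.591.

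Gene by gene, 1 of the 19227 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. It was Stk19-ps1, a pseudogene of the kinase gene Stk19 on chromosome 17 (34744469 to 34747158, GRCm38), a gene outside the rule for named genes that was chosen after its values were seen. It had 0 counts in each non-stress library and 73, 65 and 60 counts in the stress libraries, 1.53 ± 0.214 CPM (SD, n = 3; adjusted p = 0.0130). Against a floor of 3 counts over the non-stress group, it was 67.2-fold higher in stress, a bound that holds only if counts are independent. The call was lost without stress 1 (adjusted p = 0.0624), stress 2 (0.105) or stress 3 (0.0681), and a pseudogene can share reads with its parent gene. At an unadjusted p under 0.05 there were 2322 genes, 1116 higher and 1206 lower in stress, or 12.1% of those tested, where independent unchanged genes would give 5%. Other splits of the same 6 libraries into groups of 3 gave 321 to 1588 such genes. In 17.9% of genes the 3 stress values all lay on one side of the 3 non-stress values, against 10% by chance. DESeq2 called 116 genes (54 higher and 62 lower). It gave Stk19-ps1 an unadjusted p of 4.91e-12 and no adjusted p, as for 5221 genes in all. The edgeR count was 756 (577 higher and 179 lower) without non-stress 1, among them 38 of the named genes that did not pass with all libraries.

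The genes with the smallest p-values in the lower direction included interferon-inducible and MHC class I genes, although none passed edgeR's threshold. Tgtp2 and Tgtp1, near-identical interferon-inducible GTPases on chromosome 11 whose reads may have been split between them, had log2 fold changes of -2.07 (SE 0.23, adjusted p = 0.0675) and -1.90 (SE 0.24, adjusted p = 0.0944). Tgtp2 stood at 3.55 ± 0.628 CPM in non-stress and 0.845 ± 0.238 CPM in stress (SD, n = 3), which is 4.20-fold lower. Gbp4, a guanylate-binding protein of the same response on chromosome 5, stood at 8.28 ± 2.86 and 2.09 ± 0.548 CPM (log2 fold change -1.99, SE 0.28, adjusted p = 0.135). The MHC class I gene H2-D1 (chromosome 17, 35263094 to 35267497) stood at 102 ± 15.7 and 60.6 ± 2.20 CPM, with a log2 fold change of -0.75 (SE 0.10, adjusted p = 0.0944). H2-K1, another class I gene on the same chromosome with close copies that can share its reads, stood at 16.9 ± 2.18 and 10.2 ± 1.01 CPM (log2 fold change -0.74, adjusted p = 0.155). DESeq2's Wald test called all of these genes, with adjusted p = 8.30e-12 for H2-D1 and 1.39e-11 for Gbp4. In Tgtp2, Tgtp1, Gbp4, H2-D1 and H2-K1, non-stress 1 was the non-stress library nearest to the stress values. With non-stress 1 as the only non-stress library, the log2 fold changes were smaller for all of these genes. They were -1.77 for Tgtp2, -1.38 for Tgtp1, -1.25 for Gbp4, -0.47 for H2-D1 and -0.51 for H2-K1. That fit rests on 1 non-stress library and on a division found in the expression values, so it cannot test these genes.

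The other genes named in the lower direction included neuronal signalling genes. Nr4a1, an activity-induced nuclear receptor gene (chromosome 15, 101253902 to 101274795), stood at 54.1 ± 6.79 CPM in non-stress and 34.8 ± 0.864 CPM in stress, a log2 fold change of -0.64 (SE 0.08, adjusted p = 0.0944). Junb, which encodes an AP-1 transcription factor subunit, stood at 107 ± 2.50 and 88.9 ± 0.472 CPM (log2 fold change -0.27, adjusted p = 0.155). Scn2b, a sodium channel beta subunit gene, had a log2 fold change of -0.37 (adjusted p = 0.135), and Rasd2, a small GTPase gene, had one of -0.49 (adjusted p = 0.155). The protocadherin gene Pcdhga12 (-0.65), whose exons overlap those of neighbouring cluster members, and the zinc finger gene Zfp335 (-0.61) had adjusted p = 0.166 and 0.190. Myo1g had 17, 13 and 10 counts in the non-stress libraries and 0, 0 and 1 in the stress libraries (adjusted p = 0.166). DESeq2 called Nr4a1, Junb, Scn2b, Rasd2, Pcdhga12 and Zfp335 and gave Myo1g no adjusted p. Nr4a1 passed edgeR's threshold without non-stress 2 (adjusted p = 0.0281), and Nr4a1 and Tgtp2 passed it once the trend on GC content and length was taken out (both 0.0364).

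**Figure D2:**
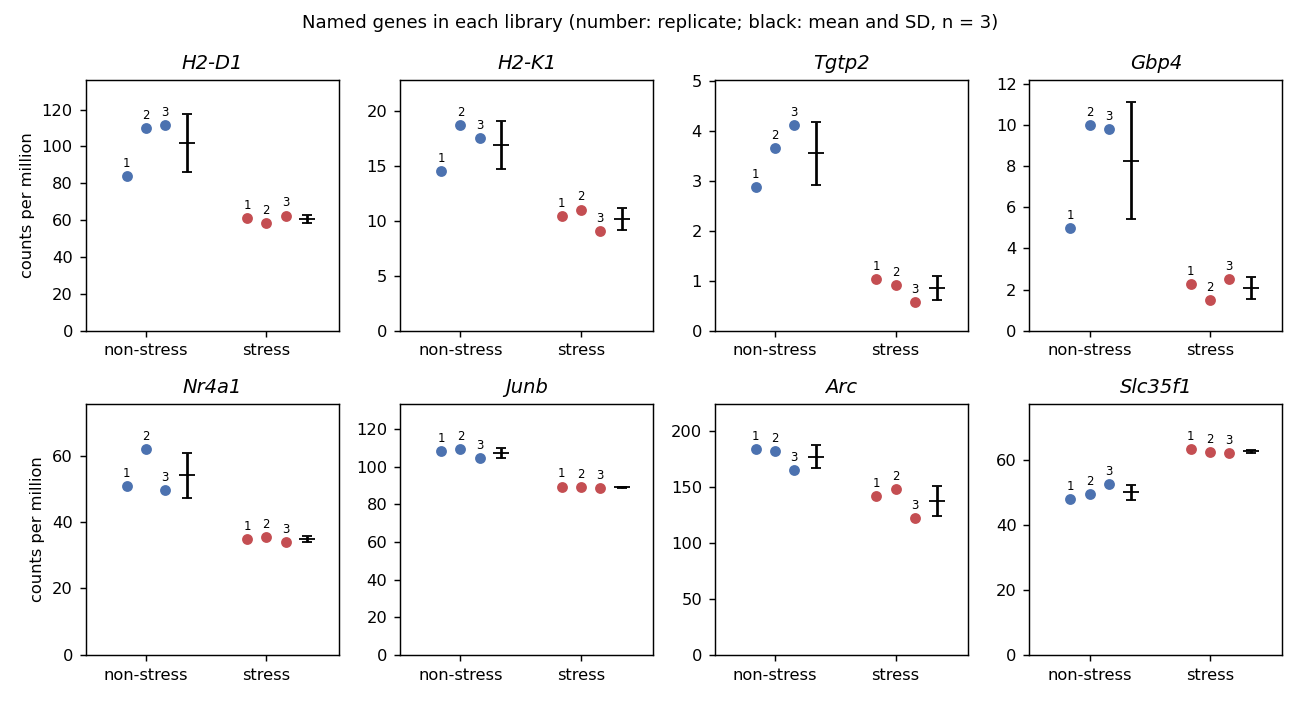
CPM of 8 named genes (vertical axes, starting at 0) are plotted for each library (blue, non-stress; red, stress; numbers give the replicate), with the mean and SD of each group in black (n = 3). For H2-D1 the means are 102 and 60.6 CPM and for Gbp4 8.28 and 2.09 CPM, with non-stress 1 the lowest non-stress library in both; none of the 8 genes passed edgeR's adjusted threshold.

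In the higher direction, none of the 12 genes named passed edgeR's threshold either. Slc35f1, a solute carrier family gene, stood at 50.1 ± 2.30 CPM in non-stress and 62.8 ± 0.577 CPM in stress, a log2 fold change of 0.32 (SE 0.05, adjusted p = 0.155). Ccn2, which encodes a matricellular growth factor, stood at 18.4 ± 0.377 and 24.3 ± 0.903 CPM (log2 fold change 0.40, adjusted p = 0.155). Ramp3, an accessory protein of calcitonin-family receptors, and Rxfp1, the relaxin receptor that couples to cyclic AMP, had log2 fold changes of 0.36 (adjusted p = 0.166) and 0.37 (adjusted p = 0.291). The cell cycle inhibitor Cdkn1a (0.42), the adhesion molecule Cadm1 (0.32), the scaffold Card10 (0.70) and the growth factor Hgf (0.89) had adjusted p-values between 0.298 and 0.309. Cuta had a log2 fold change of 0.36 (adjusted p = 0.166) and the histone gene H2aw one of 0.77 (adjusted p = 0.291), and histone genes have many near-identical copies. With non-stress 1 as the only non-stress library, log2 fold changes were smaller for Cdkn1a (0.27), Cadm1 (0.17), Card10 (0.37), Hgf (0.68) and Rxfp1 (0.35). They were larger for Slc35f1 (0.39), Ccn2 (0.41), Ramp3 (0.46), Cuta (0.47) and H2aw (0.83). Bpifa1, an airway secretory gene, had 0 counts in each non-stress library and 16, 21 and 12 in the stress libraries (adjusted p = 0.166). That was 16.6-fold higher over a floor of 3 counts for the group, if counts are independent. Gh, the pituitary growth hormone gene, had 9, 6 and 0 counts in the non-stress libraries and 337, 400 and 30 in the stress libraries (adjusted p = 0.285), and it passed without stress 3 (0.00897) or non-stress 1 (0.0302). Carry-over of pituitary tissue at dissection was not tested, so its counts cannot be assigned to the cortex. DESeq2 called 11 of these 12 genes and gave Bpifa1 no adjusted p, while limma-voom called Bpifa1 (adjusted p = 0.0150).

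Of the 37 gene lists, 36 had enough tested members. By camera with the preset correlation, 9 passed at a Benjamini-Hochberg adjusted p under 0.05, 5 higher and 4 lower in stress. With an estimated correlation 0 passed, against 3 at an unadjusted p under 0.05. With fry, which tests whether a list's genes move one way on balance, 0 passed, against 9 at an unadjusted p under 0.05. Over all genes tested, no list member passed edgeR's threshold.

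The interferon-responsive list was lower (adjusted p = 1.00e-06, or 0.406 with an estimated correlation), with 23 of its 26 tested members below 0. 4 members were lower when adjusted over the list alone (H2-D1, H2-K1, Psmb8 and B2m), and all 4 belong to antigen processing and presentation by MHC class I. Psmb8, an immunoproteasome subunit, stood at 5.27 ± 0.279 CPM in non-stress and 3.57 ± 0.532 CPM in stress. The call held without any 1 library (adjusted p at most 6.61e-05), but the non-stress libraries were not alike. Relative to the mean of all 6, the list's median was 0.031, 0.21 and 0.18 in non-stress 1, 2 and 3 and -0.13, -0.09 and -0.16 in the stress libraries. With non-stress 1 as the only non-stress library the list had a smaller median log2 fold change of -0.15. The microglia marker list, which covers the resident immune cells of the brain, did not pass (adjusted p = 0.161) and had a median log2 fold change of 0.06. Its 3 members past the threshold when adjusted over the list alone, Fcrls (0.55), Ly86 (0.31) and Tyrobp (0.30), were higher in stress. The list of inflammatory genes did not pass (adjusted p = 0.716), with a median of 0.00 and a negative test direction.

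The immediate early list was lower (adjusted p = 0.00465, or 0.406 with an estimated correlation), and 19 of its 31 members lay below 0. Adjusted over the list alone, 13 members were lower and 1 was higher. Arc, which acts at synapses, stood at 177 ± 10.3 CPM in non-stress and 137 ± 13.5 CPM in stress (log2 fold change -0.37, SE 0.07), and Fos was 1.26-fold lower in stress (-0.33, SE 0.08). Over all genes, edgeR gave adjusted p = 0.309 for Arc and 0.344 for Fos, and DESeq2 called both. The list did not pass without non-stress 1 (adjusted p = 0.0833) or after a trend on GC content and transcript length was taken out of each library (0.0707, or 0.0545 with A content added). Its median log2 difference was -0.226 for stress relative to non-stress 1 and -0.091 relative to the mean of non-stress 2 and 3. The late activity-regulated list was higher (adjusted p = 0.0335, or 0.591 with an estimated correlation), with 10 of 12 members above 0 and 0 past the threshold when adjusted over the list alone. Its leading members Inhba, Ptgs2 and Nrn1 had log2 fold changes of 0.46, 0.30 and 0.17, and the neurotrophin gene Bdnf had one of 0.14 (SE 0.09, adjusted p = 0.543) that turned to -0.030 with non-stress 1 as the only non-stress library. The late list did not pass without non-stress 2 (adjusted p = 0.218), stress 2 (0.0637) or stress 3 (0.114), or with the trend taken out (0.0816). With non-stress 1 as the only non-stress library its median log2 fold change was 0.025, against 0.095 with all libraries. Its median in non-stress 1, 0.054 relative to the mean of all libraries, lay above those of stress 1 and 2 (0.040 and 0.049).

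The circadian clock list was lower (adjusted p = 0.00128, or 0.406 with an estimated correlation), with 14 of 16 members below 0. Adjusted over the list alone, 6 members were lower, namely Cry1, Dbp, Per2, Per1, Tef and Ciart. Cry1 stood at 28.8 ± 1.68 CPM in non-stress and 22.8 ± 1.24 CPM in stress (log2 fold change -0.34, SE 0.07). Dbp, a clock-driven transcription factor gene, stood at 212 ± 7.83 and 180 ± 11.6 CPM (-0.23, SE 0.05), and Per2 at 19.8 ± 2.22 and 15.4 ± 0.388 CPM (-0.36, SE 0.09). The call held without any 1 library (adjusted p at most 0.0238) but not with non-stress 1 left out and the trend on GC content and length taken out together (0.128). Per1 belongs to this list, to the immediate early list and to the glucocorticoid-responsive list.

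Neuropeptide genes were higher as a group (adjusted p = 0.00128, or 0.406 with an estimated correlation), with 17 of 21 members above 0. Adjusted over the list alone, 6 were higher (Npy, Sst, Nts, Cck, Crh and Grp) and 1 was lower. Npy stood at 69.7 ± 4.05 CPM in non-stress and 81.6 ± 2.01 CPM in stress (log2 fold change 0.23, SE 0.05), and Sst, which encodes somatostatin, at 240 ± 26.4 and 289 ± 5.47 CPM (0.27, SE 0.07). The lower member was Pdyn, the precursor of dynorphin opioid peptides, at 51.2 ± 3.45 and 41.6 ± 1.23 CPM (-0.30, SE 0.06). The list passed without any 1 library (adjusted p at most 0.0203). Some pituitary hormone transcripts, which are not members of the list, had more counts in the stress libraries as well. Besides Gh, these were Prl (0, 0 and 0 in non-stress, 31, 39 and 7 in stress) and Pomc (108, 67 and 46, against 165, 148 and 118). Cga overlapped between the groups (4, 0 and 2, against 3, 12 and 0). A share of RNA from other tissue is therefore not excluded. Among the stress libraries these counts were lowest in stress 3, where the list's median was highest (0.11 relative to the mean of all libraries).

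Cytosolic ribosomal protein genes were higher (adjusted p = 1.32e-11, or 0.554 with an estimated correlation), with 78 of 81 members above 0. The groups overlapped by library: relative to the mean of all 6 libraries, the list's median was -0.08, -0.12 and 0.020 in non-stress 1, 2 and 3 and 0.08, 0.08 and 0.016 in stress 1, 2 and 3. Rpl37, Rpl37a and Rpl36 had log2 fold changes of 0.27, 0.35 and 0.28, and ribosomal protein genes have many processed pseudogenes that can share their reads. Nuclear-encoded respiratory chain genes were also higher (adjusted p = 1.56e-06, or 0.591 with an estimated correlation), with 72 of 81 members above 0, led by Ndufs6 (0.22), Ndufa1 (0.25) and Atp5e (0.22). Its medians also overlapped, at -0.06, -0.07 and 0.0014 in the non-stress libraries and 0.07, 0.08 and -0.020 in the stress libraries. In both lists 0 members passed when adjusted over the list alone. The respiratory chain list did not pass once the trend on GC content and length was taken out (adjusted p = 0.222), and its direction turned when non-stress 1 was left out as well (0.955). With A content added to the trend it passed as higher (0.0221), and without non-stress 1 as well it kept its direction and did not pass (0.473). Across genes, which are not independent replicates, log2 fold change was lower at higher GC content (Spearman's rho = -0.312), with a median of 0.05 in the quartile of lowest GC content and -0.07 in the highest.

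The remaining calls among the lists were weaker. Endoplasmic reticulum stress genes were higher (adjusted p = 0.0216, or 0.441 with an estimated correlation), with 12 of 14 members above 0 and leading members Pdia6 (0.18), Hsp90b1 (0.12) and Sdf2l1 (0.17). Presynaptic release genes were lower (adjusted p = 0.0452, or 0.406 with an estimated correlation), with 15 of 21 members below 0 and leading members Cplx1 (-0.19), Unc13a (-0.18) and Bsn (-0.17). In both lists 0 members passed when adjusted over the list alone. The endoplasmic reticulum list did not pass without non-stress 1 (adjusted p = 0.0510), non-stress 3 (0.0584) or stress 3 (0.101). With non-stress 1 as the only non-stress library its median log2 fold change was 0.052, against 0.094 with all libraries. The presynaptic list did not pass without non-stress 1 (adjusted p = 0.0651), non-stress 3 (0.122), stress 1 (0.0651), stress 2 (0.0686) or stress 3 (0.124), with a filter of 50 counts in 3 libraries (0.0720), or with the trend taken out (0.306). Against non-stress 1 alone its median log2 fold change was -0.054, against -0.087 with all libraries.

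**Figure D3:**
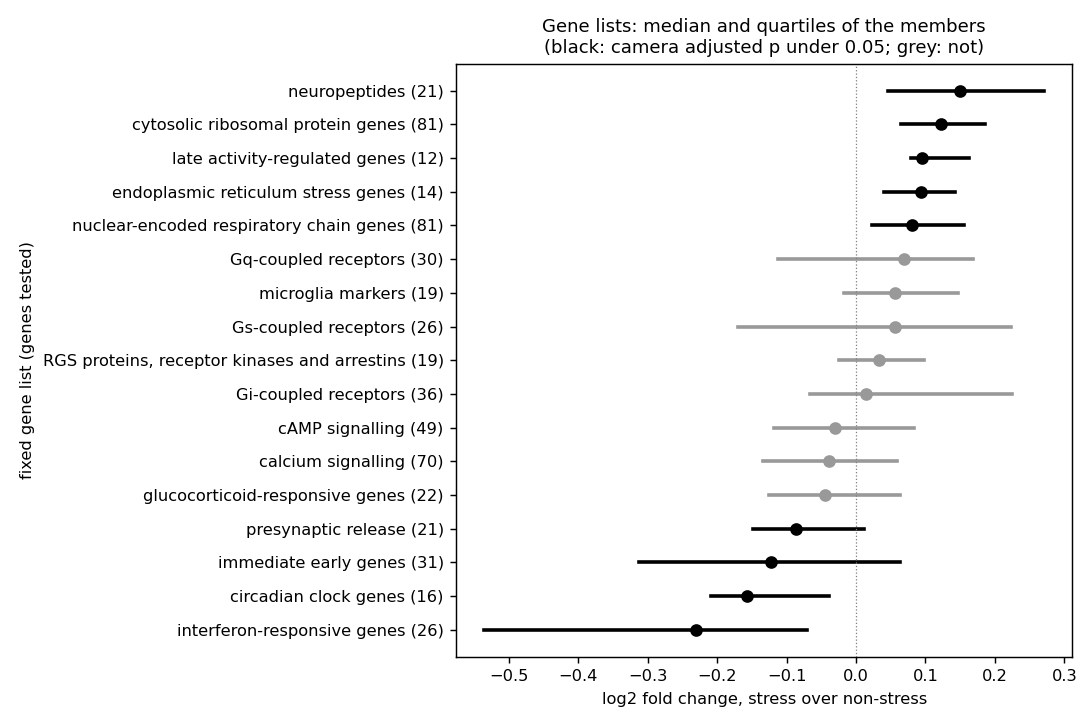
The median (point) and quartiles (line) of the members' log2 fold changes, stress over non-stress, are plotted for 17 gene lists, with the number of genes tested in brackets (black, camera adjusted p under 0.05; grey, not). Interferon-responsive genes have a median of -0.23 and neuropeptides one of 0.15; the medians of the receptor, cyclic AMP and calcium lists lie between -0.04 and 0.07, and the respiratory chain list turned direction with a GC and length trend removed and non-stress 1 left out, but not with A content in the trend.

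Among the pathways of the series title, calcium signalling genes (70 genes, adjusted p = 0.0988), cyclic AMP signalling genes (49 genes, 0.477) and receptors coupled to Gs (26 genes, 0.567), Gi (36 genes, 0.567) and Gq (30 genes, 0.426) did not pass as groups. RGS proteins, receptor kinases and arrestins, which end receptor signalling, did not pass either (19 genes, 0.524). The calcium list had a median log2 fold change of -0.04, with 44 of 70 members below 0. At the preset correlation it passed as lower without non-stress 2 (adjusted p = 0.0426). With non-stress 1 as the only non-stress library its median log2 fold change was -0.056. With all libraries its adjusted p was 0.441 with an estimated correlation. Camk2g (-0.21), Camkk1 (-0.26) and Itpr1 (-0.16), which encode calcium-dependent kinases and a calcium release channel, were its leading members, and 0 members passed when adjusted over the list alone. The adenylyl cyclase genes Adcy1 and Adcy9 were lower when adjusted over the cyclic AMP list alone. Adcy1 stood at 252 ± 5.93 CPM in non-stress and 223 ± 4.35 CPM in stress (log2 fold change -0.18, SE 0.04), and Adcy9 at 44.5 ± 2.54 and 37.5 ± 0.323 CPM (-0.25, SE 0.06). Adcy7 (0.47) was the next member by p-value. Among Gs-coupled receptors, Rxfp1 was higher and Vipr1, a receptor for vasoactive intestinal peptide, was lower (-0.37, SE 0.08) when adjusted over the list alone, and Gpr52 had a log2 fold change of 0.28. Among Gi-coupled receptors, 5 members passed when adjusted over the list alone. They included the histamine receptor Hrh3 at 140 ± 19.4 CPM in non-stress and 103 ± 2.25 CPM in stress (-0.44, SE 0.08), and the glutamate receptors Grm3 (0.48, SE 0.12) and Grm8 (0.22, SE 0.06). With non-stress 1 as the only non-stress library, Hrh3 (-0.28) and Grm3 (0.18) had smaller log2 fold changes, while Grm8 had one of 0.26. The Gq-coupled receptors Avpr1a (0.71), Chrm1 (-0.17) and Adra1b (-0.29), and Arrb1 (-0.18), Rgs4 (0.19) and Grk4 (0.45) of the RGS list, did not pass within their lists. Against non-stress 1 alone, Adra1b (-0.10), Rgs4 (0.022) and Grk4 (0.24) were smaller, while Avpr1a (0.88), Chrm1 (-0.19) and Arrb1 (-0.19) were not. None of these genes passed edgeR's test over all genes (adjusted p between 0.291 and 0.368), and DESeq2 called Rxfp1, Vipr1, Hrh3, Adcy1 and Camkk1.

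The glucocorticoid-responsive list, which tracks signalling by the stress hormone receptor, did not pass (22 genes, adjusted p = 0.567, median log2 fold change -0.04). Cdkn1a was its single member past the threshold when adjusted over the list alone, followed by Per1 (-0.42) and Mt1 (0.24). Fkbp5, a regulator of the glucocorticoid receptor, stood at 22.5 ± 2.37 CPM in non-stress and 20.6 ± 0.368 CPM in stress (log2 fold change -0.13, SE 0.08, adjusted p = 0.543). The glucocorticoid receptor gene Nr3c1 had a log2 fold change of -0.06 (SE 0.05, adjusted p = 0.661). The corticotropin-releasing hormone receptor gene Crhr1 had one of 0.09 (SE 0.10, adjusted p = 0.740), which turned to -0.10 with non-stress 1 as the only non-stress library.

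The lists for cell types and tissue boundaries did not pass, with adjusted p-values from 0.0826 for endothelial markers to 0.917 for inhibitory neuron markers. They covered excitatory and inhibitory neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium, pericytes, meninges, choroid plexus and ependyma, red blood cells, leukocytes, and the striatum and septum. Voltage-gated potassium, sodium and HCN channels did not pass (adjusted p = 0.0762), although 9 members were lower and 3 higher when adjusted over the list alone, among them Scn2b. The lists of ionotropic glutamate receptors, the GABA synapse, the perineuronal net, heat shock and cholesterol synthesis did not pass (adjusted p between 0.112 and 0.524). Some of these lists passed in alternatives, all at the preset correlation, and an estimated correlation was not run there. Oligodendrocyte and myelin markers passed as lower without non-stress 1 (adjusted p = 0.0210), while their median log2 fold change was 0.10 with non-stress 1 as the only non-stress library. With all libraries the estimated correlation between their members was 0.489, and the adjusted p with it was 0.881. Choroid plexus and ependymal markers had a median log2 fold change of -0.47 with non-stress 1 as the only non-stress library, and their median was 0.39 higher in non-stress 1 than in the mean of non-stress 2 and 3. Endothelial markers passed as lower without non-stress 1 (0.0177), and these and the myelin markers also did so with either trend taken out as well. Against non-stress 1 alone, the median log2 fold change of the endothelial markers was 0.016. The channel list passed as lower without non-stress 2 (0.0127) and with the trend including A content taken out (0.0456), and its median log2 fold change was -0.096 against non-stress 1 alone. Cholesterol synthesis passed as higher without non-stress 2 (0.0230), with the GC and length trend taken out (0.0322) and with A content added (0.0221). Its median log2 fold change was 0.085 against non-stress 1 alone. Ionotropic glutamate receptors passed as higher without non-stress 1 once either trend was taken out (0.0283, and 0.0258 with A content). Against non-stress 1 alone, their median log2 fold change was -0.019.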

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

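The removal of trends on GC content, length and A content, the separate term for non-stress 2 and 3, and the bias-adjusted dispersion and robust prior of edgeR were chosen after seeing the data. The count of genes changed by stress was 1 with all 6 libraries and ranged from 1 to 756 when 1 library was left out. The high value came from leaving out non-stress 1, and leaving out any other library gave 1 or 2. The 1 gene, Stk19-ps1, was not among those called without a stress library. DESeq2's Wald test gave 116 genes (5221 adjusted p-values were NA), limma-voom 2, voom with quality weights 14, the robust prior 4, an adjusted p under 0.1 gave 5, and an unadjusted p under 0.05 with at least 1.5-fold gave 412. With the GC and length trend removed there were 3 genes, and 979 without non-stress 1 as well. With A content added to the trend there were 3, and 824 without non-stress 1 as well. With the separate term for non-stress 2 and 3 there were 16. DESeq2 size factors, both filters and the bias-adjusted dispersion gave 1. Tests of causes for the rise without non-stress 1 are given under the other observations, and causes of the other differences were not tested.

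Replicate numbers do not pair the samples: the deviations of same-numbered libraries from their group means correlated at 0.0160, -0.0298 and 0.0209, and no label says that a number marks a shared litter or day. With the replicate block 2 genes passed, Stk19-ps1 and Gh (adjusted p = 0.000393), and 7 lists, without the late activity-regulated (0.0597) and presynaptic release (0.0737) lists; with the replicate block and the GC and length trend removed there were 4 genes and 5 lists.

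The 9 lists that passed became 6 to 11 when 1 library was left out, 0 with an estimated correlation and 0 with fry. The interferon, ribosomal protein and neuropeptide lists passed under each alternative that used camera's preset correlation. The nuclear-encoded respiratory chain genes turned direction with the GC and length trend removed and without non-stress 1 (adjusted p = 0.955). Crhr1 and Bdnf turned to log2 fold changes of -0.10 and -0.030 with the separate term for non-stress 2 and 3, and neither passed in any alternative. Over all named genes and alternatives, 1313 values kept direction and side of the threshold, 100 passed newly, 3 were lost and 2 reversed. Alternatives for normalised values and pseudocounts had nothing to act on, since the table holds counts. Depth limits Bpifa1, Myo1g and Stk19-ps1, whose libraries hold at most 73 counts.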

Other observations

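The lists in the next paragraph, the tests of a wrong group label, of the MHC region, of microglia and of genes near Stk19-ps1, the removals of trends on GC content, length and A content, and the fit with non-stress 1 alone were chosen after the results were seen.

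Interferon-inducible GTPases, which attack intracellular pathogens, were lower in stress in 17 of 18 members (camera adjusted p = 3.15e-09, or 0.0367 with an estimated correlation), with a median log2 fold change of -0.46. Adjusted over the list alone, 6 were lower, among them Ifi47 (-0.96), Irgm2 (-0.75) and Gbp2 (-0.56). MHC class I genes were lower in 14 of 15 members, with a median of -0.51 (adjusted p = 1.31e-07, or 0.0731 with an estimated correlation). Because the lists were drawn up from the leading genes, these p-values are not independent evidence. List p-values in this paragraph were adjusted over its own lists only, a smaller set than the fixed lists. They are therefore not comparable with the adjusted p-values of the fixed lists. For the GTPases, the camera p with an estimated correlation was 0.00734 before adjustment. Messenger RNAs encoded by mitochondrial DNA were higher in 13 of 13 members, with a median of 0.30 (adjusted p = 3.42e-06, or 0.265 with an estimated correlation). Non-stress 2 stood apart in this list: relative to the mean of all libraries, its median was -0.50, against 0.012 and -0.08 in non-stress 1 and 3 and 0.25, 0.16 and 0.11 in the stress libraries. Clustered protocadherins (adjusted p = 0.0840) and motile cilia genes (0.242) did not pass.

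Pituitary hormone transcripts were seen in brain tissue. Gh had 9, 6 and 0 counts in non-stress and 337, 400 and 30 in stress, Prl had 0, 0 and 0 against 31, 39 and 7, Pomc had 108, 67 and 46 against 165, 148 and 118, and Cga had 4, 0 and 2 against 3, 12 and 0. Carry-over of pituitary tissue at dissection was not tested. Bpifa1 and Stk19-ps1 were the 2 genes at 0 in one group and present at 10 or more counts in every library of the other, and other splits of the 6 libraries into groups of 3 gave up to 2 such genes.

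Leaving out non-stress 1 raised the edgeR count from 1 to 756, and in these genes non-stress 1 lay at a median of 0.926 of the way from the mean of non-stress 2 and 3 to the stress mean, as in Ccdc88a (34.9% A, longest run 17), chosen after its values were seen, with 5123, 1014 and 1063 counts in non-stress 1, 2 and 3 and 5185, 5332 and 6040 in stress. A trend on GC content and length is argued against as the whole cause, since 979 genes passed without non-stress 1 after its removal, and 527 of the 756 were among them. A wrong group label for non-stress 1 and other tissue in the dissected piece cannot be told apart from other causes: of 4 genes absent from non-stress 2 and 3 and present in every stress library, 2 were detected in non-stress 1 and 2 (Stk19-ps1 and Bpifa1) were at 0, and the largest shift of a cell type list (meningeal, 0.416, bootstrap SE 0.211) lay within its spread of the 0.555 needed. A smooth trend on A content is argued against as the whole cause, since 824 genes passed without non-stress 1 after a trend on A content, GC content and length was removed. The correlation with A content (rho = 0.289) exceeded that with T content by 0.0705 (bootstrap SE 0.00834), under the bound of 0.1 set beforehand for priming inside A-rich transcripts. Content over a whole transcript does not measure local runs of A, so priming is not excluded by it. The 577 genes called higher had a median A content of 30.9% and T content of 27.3%, against 25.5% and 24.6% over all genes tested, and a median longest run of A of 7 against 6. The top 5% of genes by A content lay at a median of -0.012, -0.32 and -0.17 in non-stress 1, 2 and 3 relative to the stress mean. Non-stress 2 minus non-stress 3 also correlated with A content (rho = -0.310). No biological explanation was tested for this division within the non-stress group.

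Lower expression of interferon-responsive and MHC class I genes may reflect a response of the tissue to stress, as a hypothesis found and tested on the same data. A genetic difference at the MHC region as the whole cause stays open, since its test depended on the correlation used. The 21 list members outside chromosome 17 had a median of -0.19. They were lower as a group by camera at the preset correlation (p = 3.52e-05), but did not pass with an estimated correlation (p = 0.0612). Fewer microglia are argued against by their markers, whose median log2 fold change was 0.0568 (quartiles -0.017 and 0.15, 11 of 19 higher and 8 lower). Endothelial markers were lower in 11 of 15 members (median -0.08, camera adjusted p = 0.0826), and a part of other cell types was not tested. The endothelial median was 0.016 with non-stress 1 as the only non-stress library. The GC and length trend is argued against only as the source of the list's call at the preset correlation. There the camera adjusted p was 1.00e-06 before and 2.59e-07 after its removal. An estimated correlation was not run after the removal. The division of the non-stress libraries stays open, since non-stress 1 lay at a median of -0.24 relative to non-stress 2 and 3 over this list, and stress at -0.15 relative to non-stress 1 alone. Reads shared among class I copies were not tested.

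Stk19-ps1 was present in the stress libraries alone, and reads shared with Stk19 stay open: the sum of both genes was higher by 1.56 CPM (SE 1.11), against a gain of 1.53 CPM in the pseudogene. A difference between animals at this part of chromosome 17 also stays open. Of 106 tested genes within 1000000 bases, 17 (16.0%) had an unadjusted p under 0.05, against 12.1% of the other genes (Fisher's exact test, p = 0.229). The 17 included H2-D1, H2-K1, Psmb8 and Psmb9 of the interferon-responsive list, so the count does not bear on Stk19-ps1 alone. No biological explanation was tested for this gene.

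The 6 libraries form 10 splits into groups of 3, too few for a share under 0.05. The real split gave 1 gene and the highest other split 1, with 3 of the 10 splits giving as many. For lists the real split gave 9 and the highest other 7, so 1 split gave as many. At an unadjusted p under 0.05 the real split gave 2322 genes and the highest other 1588, which set non-stress 2 and 3 with stress 3 against non-stress 1 with stress 1 and 2.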
